A study of Bos taurus and Bos grunniens x Bos taurus and Bos grunniens with 18 samples.

How the data were processed

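Testes of 9 animals, 3 cattle, 3 cattle-yaks and 3 yaks, each 4 years old, were sequenced as directional libraries depleted of ribosomal RNA, with paired reads of 125 nt per the labels. The tissue was frozen in liquid nitrogen and its RNA extracted with TRIzol. Per the submitters' processing notes, the tools were Trimmomatic, HISAT2 (2.0.5), StringTie (1.3.4), Cufflinks and Bowtie and the genome build was UMD3.1, a cattle build, with no role given for each tool. The mRNA values were deposited as FPKM, fragments scaled by transcript length and by the mapped fragments of the library, computed by the authors for 22118 protein-coding transcripts, and which tool gave them is not stated. The circRNA table was deposited with a read count for each circRNA and library, per the file headers, and the caller is not given in the sources used here. Its TPM columns, made by the authors per the file headers, are the reads of a circRNA scaled to the same total of table reads in every library, with no length term. Group means in 3 unnamed columns were not used. The circRNA table has no value of 1, and each circRNA has at least 2 reads in all 3 libraries of at least 1 group, so it had been filtered on the groups.

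Samples were grouped by the species or hybrid of their title. FPKM values were summed over the transcripts of a gene, which gave 19994 genes, 16458 of them with a symbol. Genes with an FPKM of at least 1 in at least 3 libraries were tested, 14091 in all. In 93 genes at least 1 library was at 0 while another was above 10 FPKM. The 12 housekeeping genes had no value at 0. Read depth behind the FPKM is unknown: a relative depth of 0.883 to 1.05 was read from low values, but only 2.60 to 3.87% of low values lay at that ratio, so whole reads were not recovered and no count test was used for mRNA. Log2(FPKM + 1) was fitted with limma 3.58.1 in R 4.3.3, with a term for group over all 9 libraries and empirical Bayes moderation with a trend. The 4 contrasts were cattle-yak against cattle, cattle-yak against yak, yak against cattle, and cattle-yak against the mean of both parents. Two-sided p-values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 is named a call.

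Genes called the same way against both parents were counted. They were set against 20 simulations in which no group differed and against the overlap of independent lists of the same sizes. The 22 gene lists were written before the data were examined. They cover spermatogonia, meiotic prophase, late spermatocytes, the spermatid nucleus and kinases, acrosome, flagellum, the piRNA pathway, Sertoli cells, Leydig cell steroidogenesis, tubule smooth muscle, extracellular matrix, endothelium, macrophages, lymphocytes, blood, epididymis and rete testis epithelium, apoptosis, heat shock, immediate early genes, the interferon response, hypoxia and housekeeping genes. Of 434 listed genes 395 were matched by symbol and 357 tested. Lists were tested with camera of limma at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. Camera compares a list with all other genes, while fry asks whether the genes of a list move on balance one way.

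CircRNA counts were tested with the quasi-likelihood test of edgeR 4.0.16 with TMM factors, for circRNAs with at least 5 reads in at least 3 libraries, 3730 in all, in the same contrasts. Numbers of circRNAs per library were compared by exact two-sided permutation tests, for which 3 against 3 libraries give no p under 0.1. Data were simulated from these libraries with 200 genes changed, and with 100 circRNAs changed by each size. There limma called 16.4, 91.0 and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale between cattle-yak and cattle. For circRNAs edgeR called 3 and 45% of those changed by 1 and 2. The adjustment is stricter where few features change, and in the real data 84.4% of genes and 28.4% of circRNAs were called against cattle. The simulated shares therefore do not give the recovery in the real data. Of the mRNA calls in the simulated data 6.16% against cattle and 4.26% against yak were false, and of the circRNA calls 4 and 9.43%.

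Genes named in the text were chosen by a rule fixed before the data were examined. Among called genes with a symbol, libraries that did not overlap and a mean of at least 5 FPKM in the higher group, it took the 10 highest and 10 lowest by the smaller absolute log2 fold change for genes called the same way against both parents, and the 10 highest and 10 lowest between yak and cattle. It took 5 and 5 among genes called against 1 parent and not the other. For each gene list it took the 3 most abundant tested members, whether called or not. For circRNAs it took 5 and 5 against both parents and 5 and 5 between yak and cattle, with a mean of at least 10 reads in the higher group. Some genes that the rule took are not given in the text. Other genes are said in the text to be chosen after their values were seen.

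Alternatives for mRNA, all fixed before the data were examined, were a pseudocount of 0.1, no filter, a minimum of 5 FPKM, quantile normalisation, median-ratio scaling, rescaling to the same total without the 1% most abundant genes, an absolute log2 fold change of at least 1, fits of the compared groups alone, the replicate number as a block, and leaving out each library. For circRNAs they were DESeq2 1.42.0, library totals without TMM, no filter, at least 10 reads, limma on the deposited TPM, the same fold change minimum, fits of the compared groups alone, the block, and leaving out each library. Detection was also counted at 1 and at 5 reads and after thinning. The 9 small RNA libraries of the series are not analysed here, since no column of the tables used belongs to them. The planned comparison of circRNAs with their host genes was not run, because the circRNA table used here gives neither host genes nor positions. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.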

Results

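Testes of 4-year-old cattle, yaks and cattle-yaks were profiled by RNA sequencing, with 3 animals of each kind, kept by the same cooperative and castrated for the study. Cattle-yaks are hybrids of cattle and yak in which females are fertile and males are sterile, and the labels do not say which parent was the dam. The labels describe the replicates as separate animals, so the spread within a group is a spread between animals. The series asks which mRNAs and circular RNAs differ between the hybrid and its parent species, and values were deposited for 9 libraries. The mRNA table held FPKM for 19994 genes, of which 14091 reached an FPKM of 1 in at least 3 libraries and were tested. Summed FPKM per library lay between 408528 and 481551. The 10 most abundant genes took between 3.60 and 10.1% of that sum. The circular RNA table held read counts for 5730 circular RNAs (circRNAs, closed loops made by back-splicing), of which 3730 had at least 5 reads in at least 3 libraries. Its reads summed to 54099, 50541 and 54317 in the cattle libraries, 50533, 60791 and 65174 in the cattle-yak libraries, and 52471, 44469 and 48286 in the yak libraries. Values below are mean ± SD with n = 3 per group, and fold changes in mRNA are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

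Hybrid libraries stood far from both parents. The first principal component of log2(FPKM + 1) held 87.8% of the variance and set the cattle-yak libraries, at 120.2, 122.7 and 146.4, apart from the cattle and yak libraries, which lay between −86.9 and −57.4. The second component held 7.21% and parted cattle from yak. Across genes, the correlation of 2 libraries was 0.977 to 0.990 within a group, 0.948 to 0.956 between cattle and yak, and 0.511 to 0.676 between cattle-yak and a parent, where genes are not independent replicates. Cattle-yak replicate 3 and yak replicate 1 lay farthest out on the first component. Without cattle-yak replicate 3 the counts of genes called with limma were 11588 against cattle and 11865 against yak, and without yak replicate 1 they were 11927 and 11801.

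**Figure D1:**
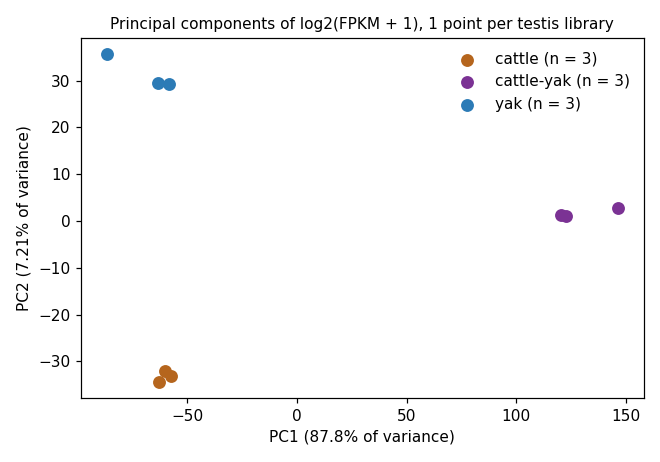
First and second principal components of log2(FPKM + 1) over the genes tested, with 1 point per testis library and 3 libraries per group. The cattle-yak libraries lie between 120.2 and 146.4 on the first component, which holds 87.8% of the variance, and all cattle and yak libraries lie at −57.4 or below.

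The comparison of the hybrid with each parent asked which genes depart from both. Genes that package sperm DNA fell furthest of the named genes. PRM1 (ENSBTAG00000021493), a protamine that replaces histones in the sperm nucleus, had 15597 ± 4844 FPKM in cattle, 13901 ± 370 in yak and 24.2 ± 18.1 in cattle-yak, a log2 change of −9.61 ± 0.57 (SE) against cattle (limma, adjusted p = 1.88e-07). TNP1 (ENSBTAG00000019003), a transition protein that precedes the protamines, fell from 3715 ± 990 FPKM in cattle and 4804 ± 568 in yak to 14.4 ± 10.9. In the opposite direction, CYP17A1 (ENSBTAG00000014335), an enzyme of androgen synthesis in Leydig cells, rose from 13.8 ± 3.38 FPKM in cattle and 14.6 ± 5.24 in yak to 177 ± 9.17. Its log2 change was 3.62 ± 0.24 (SE) against cattle (limma, adjusted p = 3.87e-07) and 3.57 ± 0.24 against yak (adjusted p = 3.86e-07).

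The other named genes that fell against both parents each had a log2 change below −7 in both comparisons. TNP2, a second transition protein, was at 925 ± 42.8 FPKM in cattle, 980 ± 59.3 in yak and 2.35 ± 2.27 in cattle-yak. PRM2, the second protamine, was at 795 ± 15.2, 999 ± 63.6 and 2.16 ± 2.06 in the same order. HMGB4, a testis high-mobility-group protein, fell from 913 ± 68.9 and 1032 ± 134 to 4.73 ± 3.46 FPKM. OAZ3, a testis ornithine decarboxylase antizyme, fell from 829 ± 148 and 789 ± 102 to 4.22 ± 2.98 FPKM. SMCP, a protein of the sperm mitochondrial capsule, fell from 428 ± 133 and 397 ± 59.7 to 1.75 ± 1.38 FPKM. CABS1, a calcium-binding protein of elongating spermatids, fell from 412 ± 45.7 and 351 ± 36.9 to 1.24 ± 0.93, and SPEM1, which acts in sperm maturation, from 236 ± 8.73 and 288 ± 13.4 to 0.72 ± 0.51. C25H16orf82 fell from 750 ± 101 FPKM in cattle and 621 ± 50.2 in yak to 1.95 ± 1.22. Other named genes rose against both parents. IGFBP2, a binding protein of insulin-like growth factors, rose from 14.3 ± 2.80 FPKM in cattle and 32.2 ± 12.4 in yak to 230 ± 18.8. TF, the iron carrier transferrin that Sertoli cells secrete, rose from 13.8 ± 2.20 and 16.4 ± 6.17 to 133 ± 15.8. APOE, a lipid carrier, rose from 29.8 ± 9.21 and 46.4 ± 23.9 to 289 ± 82.5, and KITLG, the Sertoli cell ligand of the spermatogonial receptor KIT, from 3.67 ± 0.51 and 3.86 ± 1.73 to 30.9 ± 5.67. CRABP2, a retinoic acid binding protein, ACSM1, a mitochondrial acyl-CoA synthetase, RHOB, a small GTPase, TNFRSF12A, a receptor of the tumour necrosis factor family, and ADCYAP1R1, a receptor of the neuropeptide PACAP, rose by between 2.68 and 4.02 on the log2 scale in the 2 comparisons.

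Germ cell lists parted by stage. All 24 tested members of the spermatid nucleus and kinase list fell against both parents, with a median log2 fold change of −6.15 against cattle and −6.14 against yak. The limma set test camera gave adjusted p = 6.07e-15 and 1.42e-14, and adjusted p = 0.449 and 0.459 with an estimated correlation. Of 23 acrosome genes, 22 fell against each parent, with medians of −4.31 and −4.10 (camera, adjusted p = 5.28e-12 against cattle and adjusted p = 6.03e-12 against yak). With an estimated correlation the adjusted p was 0.449 and 0.459. ADAM2, a sperm surface protein of fertilisation, fell from 211 ± 18 FPKM in cattle and 244 ± 38.8 in yak to 21.9 ± 11.5. ADAM32, of the same family, fell from 417 ± 40 and 460 ± 33.6 to 35 ± 17.4, and IZUMO4, of the sperm-egg fusion family, from 368 ± 34 and 292 ± 14.1 to 19.8 ± 10.9. The member that was not called, TEX101 (chosen after its values were seen), had log2 changes of 0.18 and −0.06. All 40 flagellum genes fell, with medians of −3.27 and −3.23 (camera, adjusted p = 8.16e-16 and 1.41e-15, and adjusted p = 0.449 and 0.459 with an estimated correlation). ODF2, an outer dense fibre protein of the tail, fell from 620 ± 142 and 377 ± 32.6 to 44.2 ± 14.6 FPKM. ROPN1, a sheath protein, fell from 455 ± 14 and 441 ± 34.5 to 11.1 ± 6.31, and SPA17, a sperm surface protein, by 3.27 ± 0.27 (SE) on the log2 scale against cattle. These 3 lists kept their direction under all 3 other scalings of the libraries.

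The change was smaller and mixed in earlier stages. Of 12 late spermatocyte genes 10 fell and 2 rose against each parent, with medians of −1.12 against cattle and −1.32 against yak (camera, adjusted p = 0.00388 and 0.00319, and adjusted p = 0.481 and 0.477 with an estimated correlation). CLGN, a chaperone of the germ cell endoplasmic reticulum, fell from 993 ± 101 FPKM in cattle and 1149 ± 105 in yak to 232 ± 55.1, and LDHC, the germ cell lactate dehydrogenase, from 423 ± 53.7 and 398 ± 57.2 to 71.6 ± 34.5. CETN1, a centrin, fell by 4.31 ± 0.44 (SE) on the log2 scale against cattle. The members that rose were AURKC, a meiotic kinase, and CCNB3, a meiotic cyclin, both chosen after their values were seen. In the piRNA pathway, which silences transposons in germ cells, 15 of 21 genes fell and 3 rose against cattle, and 16 fell and 3 rose against yak, with medians of −1.21 and −1.11 (camera, adjusted p = 0.00134 and 0.000385, and adjusted p = 0.706 and 0.649 with an estimated correlation). DDX4, the germ cell helicase VASA, fell from 252 ± 18 and 217 ± 21.5 to 82.3 ± 19.7 FPKM. DDX25, another testis helicase, fell from 461 ± 17.8 and 485 ± 31.4 to 90.5 ± 35.3, and GTSF1, a piRNA factor, from 345 ± 25.2 and 348 ± 37.2 to 57.8 ± 18.5. Of 31 meiotic prophase genes, 6 rose and 12 fell against each parent, and the set test was not passed (camera, adjusted p = 0.0644 and 0.0695). TEX11, a recombination factor, rose from 55.2 ± 2.09 and 45 ± 5.78 to 199 ± 34.3 FPKM while SYCE3, part of the synaptonemal complex, fell from 77.5 ± 18.2 and 162 ± 14.8 to 38.4 ± 13.5. SPATA22, which acts in recombination, was at 84.6 ± 11.1, 79.7 ± 8.27 and 104 ± 37.0 FPKM in cattle, yak and cattle-yak and was not called. Without cattle-yak replicate 3 it was called higher against both (limma, adjusted p = 0.0041 and 0.00172). Median-ratio scaling left 2 meiotic genes higher and 18 lower against cattle, and 2 and 19 against yak.

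Spermatogonial genes rose. Of 15 tested, 13 rose and 1 fell against cattle and 14 rose and 1 fell against yak, with medians of 1.40 and 1.48 (camera, adjusted p = 0.0261 and 0.0135, and adjusted p = 0.706 and 0.649 with an estimated correlation). DMRT1, a transcription factor of spermatogonia and Sertoli cells, rose from 39.6 ± 5.38 FPKM in cattle and 31.5 ± 6.53 in yak to 159 ± 20.8. DAZL, an RNA-binding protein of germ cells, rose from 89.1 ± 3.96 and 64.1 ± 2.39 to 164 ± 23.6, and TKTL1, a transketolase-like protein, from 36.2 ± 1.53 and 30.8 ± 5.37 to 128 ± 25. The member that fell was LIN28B, an RNA-binding protein (chosen after its values were seen). The direction of this list was the same under the other scalings, with 11 higher and 1 lower against cattle after median-ratio scaling.

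Markers of the somatic cells of the testis rose with them. Of 21 Sertoli cell genes 19 rose and 0 fell against each parent, with medians of 1.76 and 1.95 (camera, adjusted p = 0.00313 and 0.00302, and adjusted p = 0.706 and 0.649 with an estimated correlation). CLU, the secreted chaperone clusterin, rose from 305 ± 50 FPKM in cattle and 330 ± 33.4 in yak to 1198 ± 111. CLDN11, a tight junction protein of the blood-testis barrier, rose from 85.2 ± 9.57 and 82.7 ± 28.6 to 315 ± 15, and FATE1 from 182 ± 27.2 and 213 ± 43.9 to 504 ± 26.9. In the Leydig cell steroidogenesis list 16 of 17 genes rose and 1 fell against each parent, with medians of 1.96 and 1.99 (camera, adjusted p = 0.0109 and 0.00857, and adjusted p = 0.706 and 0.649 with an estimated correlation). INSL3 (ENSBTAG00000025775), a peptide hormone of Leydig cells, rose from 233 ± 74.2 and 411 ± 171 to 1441 ± 306 FPKM. CYB5A, an electron carrier of steroid synthesis, rose from 59.4 ± 12.5 and 39.9 ± 5.35 to 103 ± 21.8, a call that median-ratio scaling ended against cattle (limma, adjusted p = 0.291). The member that fell was SRD5A1, a steroid reductase, chosen after its values were seen.

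Stromal, vascular and leucocyte lists were tested next. Of 21 extracellular matrix genes 20 rose and 1, COL4A2 (a basement membrane collagen chosen after its values were seen), fell against cattle, and 21 rose against yak, with medians of 1.46 and 2.18 (camera, adjusted p = 0.0202 and 0.00279, and adjusted p = 0.720 and 0.649 with an estimated correlation). SPARC, a matrix glycoprotein, rose from 99.0 ± 6.59 FPKM in cattle and 88.2 ± 39.7 in yak to 504 ± 117. MGP, a matrix calcification inhibitor, rose from 107 ± 23.2 and 74.5 ± 42.3 to 332 ± 53.0, and COL6A1, a collagen, from 10.9 ± 1.56 and 7.40 ± 1.84 to 65.2 ± 14.9. Of 11 smooth muscle genes of the tubule wall 11 rose against cattle and 10 against yak, with medians of 1.10 and 1.59, and the set test was passed against yak only (camera, adjusted p = 0.0531 against cattle and 0.0346 against yak, and adjusted p = 0.649 against yak with an estimated correlation), with no test of the difference. ACTA2, smooth muscle actin, rose from 29.3 ± 6.44 and 20.2 ± 10.3 to 90.3 ± 13.7 FPKM, and TAGLN and MYH11, contractile proteins, rose as well. Among 11 endothelial genes 9 rose and 1 fell against cattle and 8 rose and 2 fell against yak (camera, adjusted p = 0.216 and 0.389). KDR, a receptor of vascular growth factor, rose from 3.51 ± 0.82 and 2.23 ± 1.16 to 8.68 ± 0.66 FPKM, as did CLDN5, an endothelial tight junction protein. VWF, a clotting factor of endothelium, fell to 1.70 ± 0.20 from 2.97 ± 1.26 and 10.9 ± 1.64. Its call against cattle was lost without cattle replicate 2 (limma, adjusted p = 0.155) and without cattle-yak replicate 1, 2 or 3 (adjusted p = 0.0527, 0.106 and 0.0643).

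Of 15 macrophage genes 8 rose and 2 fell against cattle, and 13 rose and 2 fell against yak (camera, adjusted p = 0.615 and 0.29). MRC1, the macrophage mannose receptor, rose from 25.9 ± 3.36 FPKM in cattle and 31.4 ± 9.85 in yak to 114 ± 10, while AIF1, a calcium-binding protein of macrophages, fell from 107.5 ± 1.71 and 131 ± 15 to 7.955 ± 3.04. CD74, the invariant chain of antigen presentation, rose from 26.6 ± 3.97 and 19.7 ± 8.35 to 53 ± 17.5. Its call against cattle was lost without cattle replicate 3 or cattle-yak replicate 2 (limma, adjusted p = 0.0554 and 0.0661) and under median-ratio scaling (adjusted p = 0.251). Among 10 lymphocyte genes 6 rose and 0 fell against cattle and 8 rose and 1 fell against yak (camera, adjusted p = 0.425 and 0.281), but only 1 was called higher against cattle after median-ratio scaling. PTPRC, the leucocyte antigen CD45, rose from 4.08 ± 0.71 and 2.23 ± 0.61 to 11.9 ± 2.39 FPKM. CCL5, a chemokine, was called against yak, and against cattle when yak replicate 1 was left out (limma, adjusted p = 0.0358). IL7R, a cytokine receptor of T cells, fell against yak only, from 7.31 ± 1.48 to 1.285 ± 1.15 FPKM, with no test of the difference between the comparisons. All 3 blood genes fell, with medians of −2.06 and −1.68 (camera, adjusted p = 0.0413 and 0.0346, and adjusted p = 0.449 and 0.459 with an estimated correlation), and quantile normalisation ended both set calls (adjusted p = 0.0623 and 0.0549). S100A12, a neutrophil protein, fell from 12 ± 7.99 and 41.6 ± 3.19 to 0.72 ± 0.18 FPKM, and AHSP, which stabilises alpha-haemoglobin, fell from 4.12 ± 0.25 FPKM in cattle to 0.88 ± 0.32. Of 4 genes of epididymis and rete testis epithelium 2 rose and 1 fell against each parent (camera, adjusted p = 0.987 and 0.925). The list's median against yak was 0.42 and its mean 0.39 while camera put the list downward, and after median-ratio scaling the medians were −0.02 and −0.11. KRT18, a keratin, rose from 1.55 ± 0.61 and 2.90 ± 1.26 to 10.3 ± 1.33 FPKM. KRT8, its partner, also rose, though not after median-ratio scaling against cattle (limma, adjusted p = 0.121). EPCAM, an epithelial adhesion molecule, was at 112 ± 19.5, 137 ± 6.84 and 122 ± 20.4 FPKM in cattle, yak and cattle-yak and was called in neither comparison. Median-ratio scaling called EPCAM lower against both (limma, adjusted p = 0.0224 and 0.000681), and quantile normalisation called it higher against cattle (adjusted p = 0.0329).

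Stress and control lists were tested as well, and RNA quality itself was not measured here. Of 14 apoptosis genes 11 rose and 0 fell against cattle and 12 rose and 1 fell against yak, with medians of 1.29 and 1.49 (camera, adjusted p = 0.0278 and 0.0263, and adjusted p = 0.706 and 0.649 with an estimated correlation). CDKN1A and MDM2, targets of p53, rose from 15.6 ± 1.11 and 12 ± 1.90 FPKM in cattle to 44.9 ± 4.29 and 34.3 ± 1.88. APAF1, the apoptosome scaffold, rose from 21.3 ± 1.65 to 34.2 ± 3.99 but was not called after median-ratio scaling (limma, adjusted p = 0.337 against cattle and 0.132 against yak). Of 12 immediate early genes 10 rose against cattle and 11 against yak and 0 fell, with medians of 1.31 and 1.38 (camera, adjusted p = 0.0517 and 0.0263, and adjusted p = 0.649 against yak with an estimated correlation). JUN and JUNB, transcription factors of the early response, rose from 5.40 ± 0.87 and 3.72 ± 1.01 FPKM in cattle to 22.9 ± 1.27 and 12.9 ± 1.62. DUSP1, a phosphatase of the same response, was at 15.1 ± 1.67, 11.8 ± 1.23 and 15.6 ± 2.70 FPKM in cattle, yak and cattle-yak, and its log2 change of 0.36 against yak (limma, adjusted p = 0.0355) was −0.23 after median-ratio scaling and was not called without cattle-yak replicate 2 or 3 or yak replicate 1 or 2 (adjusted p = 0.0588, 0.141, 0.111 and 0.0522) or after quantile normalisation (adjusted p = 0.371). Median-ratio scaling called DUSP1 lower against cattle (limma, adjusted p = 0.00382). Among 12 heat shock genes 8 rose and 2 fell against cattle and 9 rose and 2 fell against yak (camera, adjusted p = 0.395 and 0.287). HSPA8, a constitutive chaperone, rose from 193 ± 10.7 and 161 ± 30.2 to 811 ± 46.4 FPKM. HSPA5, a chaperone of the endoplasmic reticulum, was at 355 ± 9.01, 390 ± 45 and 404 ± 118 FPKM in cattle, yak and cattle-yak and was called in neither comparison, but lower against yak after median-ratio scaling (limma, adjusted p = 0.0102). HSP90AA1, another chaperone, was called higher against yak and not against cattle, by 0.40 (limma, adjusted p = 0.0328), which was −0.24 after median-ratio scaling. That scaling called it lower against cattle, at −0.64 (limma, adjusted p = 0.00492). Its call against yak was lost after quantile normalisation and without a filter (limma, adjusted p = 0.119 and 0.0784), without cattle-yak replicate 1 or 2 (adjusted p = 0.0859 and 0.132) and without yak replicate 1, 2 or 3 (limma, adjusted p = 0.0504, 0.104 and 0.0537). That call was also lost with the replicate number as a block and with the compared groups alone (limma, adjusted p = 0.056 and 0.0566). Of 15 interferon response genes 6 rose and 2 fell against cattle and 11 rose and 2 fell against yak (camera, adjusted p = 0.761 and 0.518), and median-ratio scaling left 2 higher and 3 lower against cattle. IFI27, an interferon-induced gene, was at 18.6 ± 7.34, 13.8 ± 9.38 and 25.9 ± 6.70 FPKM in cattle, yak and cattle-yak and was called in neither comparison. Against yak it was called without cattle replicate 3, cattle-yak replicate 1 or yak replicate 3 (limma, adjusted p = 0.0389, 0.0422 and 0.00482) and after rescaling without the most abundant genes (adjusted p = 0.0429). Of 13 hypoxia response genes 8 rose and 5 fell against each parent (camera, adjusted p = 0.886 and 0.86), and the most abundant members, LDHA, PDK1 and CA9, of lactate, pyruvate and bicarbonate metabolism, fell by 0.96, 1.53 and 3.48 on the log2 scale against cattle. Of 12 housekeeping genes 9 rose and 1 fell against each parent (camera, adjusted p = 0.0901 and 0.136). RPLP0, a ribosomal protein, rose from 551 ± 29.9 and 501 ± 61.7 to 1021 ± 116 FPKM. PPIA, a folding enzyme, was at 490 ± 33.3, 677 ± 48.2 and 592 ± 40.5 FPKM in cattle, yak and cattle-yak and was called in neither comparison. It was called higher against cattle without cattle-yak replicate 1 and after rescaling without the most abundant genes (limma, adjusted p = 0.0415 and 0.0393). Against yak it was called lower after quantile normalisation and median-ratio scaling (limma, adjusted p = 0.0423 and 0.000186).

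**Figure D2:**
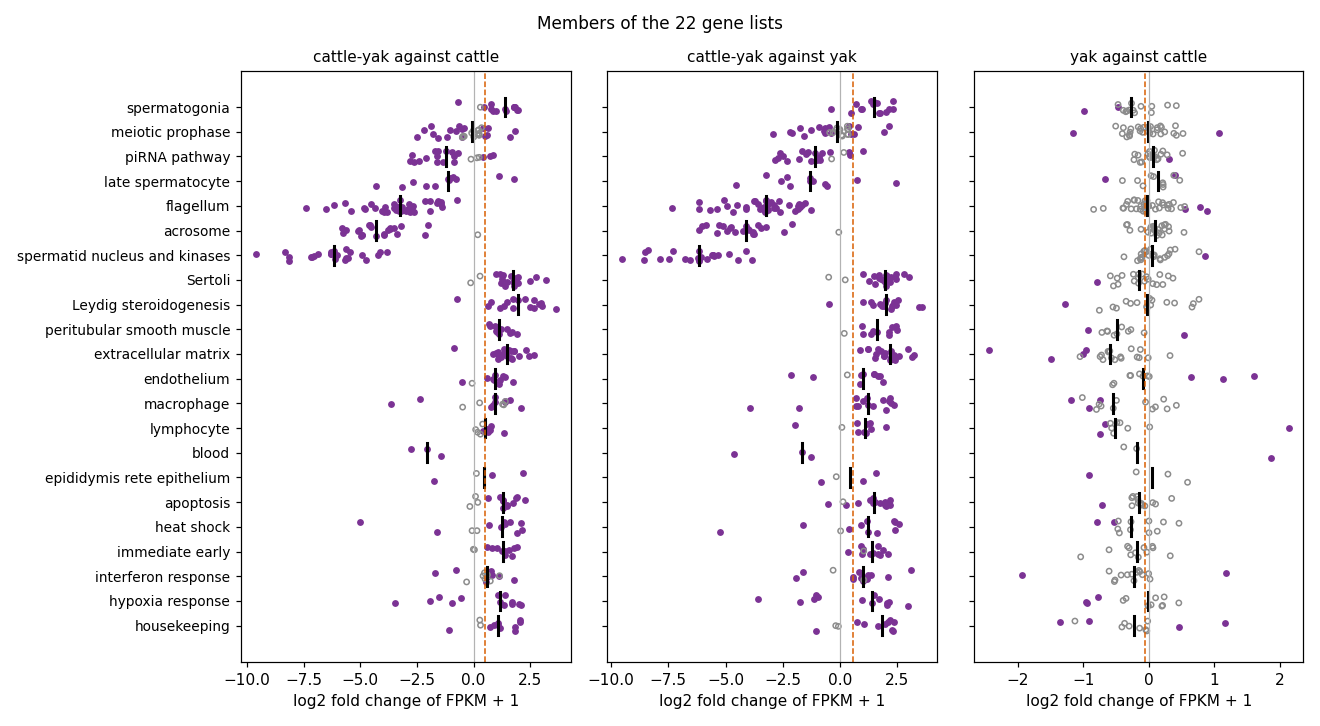
Log2 fold change of FPKM + 1 of each tested member of the 22 gene lists in the 3 pairwise comparisons, with purple points for genes called by limma at an adjusted p under 0.05, open grey points for others, a black bar at the list median and a dashed line at the median of all genes tested. All 24 spermatid and 40 flagellum genes lie below 0 in both hybrid comparisons, with list medians of −6.15 and −3.27 against cattle, while the Sertoli and Leydig medians lie at 1.76 and 1.96, and these 4 medians keep their sign under the 3 other scalings while that of the epididymis list turns from 0.46 to −0.02 after median-ratio scaling.

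In all, limma called 11894 of 14091 genes between cattle-yak and cattle, with 7670 higher and 4224 lower in cattle-yak, and 12116 between cattle-yak and yak, with 7794 higher and 4322 lower. Falls of 8-fold or more outnumbered such rises, with 814 genes at least 8-fold lower and 29 at least 8-fold higher against cattle, and 857 and 27 against yak. Libraries of the groups did not overlap for 12141 genes (86.2%) against cattle and 12431 (88.2%) against yak, where chance gives 10%. The median log2 change of all genes tested was 0.50 against cattle and 0.54 against yak. Median-ratio scaling moved these medians to 0.0197 and 0.00261 and the split to 5550 higher and 5710 lower of 11260 genes against cattle, and 5696 and 5912 of 11608 against yak, so that 49.3% rather than 64.5% and 49.1% rather than 64.3% of calls were higher. Relative to the median of all genes, list medians against cattle were −6.64 for spermatid, −4.81 for acrosome, −3.77 for flagellum, −1.71 for piRNA, −1.61 for late spermatocyte and −0.58 for meiotic genes. They were 0.90 for spermatogonia, 1.26 for Sertoli, 1.46 for Leydig, 0.96 for matrix, 0.60 for smooth muscle and 0.000209 for lymphocyte genes. Medians of the control and stress lists lay above 0 as well. The heat shock, hypoxia, interferon and housekeeping lists passed camera against neither parent. Before this subtraction the housekeeping median was 1.07 against cattle and 1.81 against yak. Against cattle the others were 1.31 for immediate early, 1.29 for apoptosis, 1.27 for heat shock, 1.17 for hypoxia and 0.585 for interferon genes, beside 1.46 for matrix and 1.10 for smooth muscle. The counts of called members adjusted over the list alone were those given above except for 5 higher and 10 lower meiotic genes against cattle and, against yak, 3 and 10 meiotic, 3 and 17 piRNA, 12 and 0 immediate early and 12 and 2 interferon genes. With the preset correlation of 0.01, camera passed 11 of 22 lists against cattle and 13 against yak, and with an estimated correlation it passed 0 (0 of the 66 tests of 3 comparisons had an unadjusted p under 0.05). The further test fry of limma passed 38 of the 66. Fry does not compare a list with the other genes, so a list can pass because most genes moved. The housekeeping list passed it too (fry, adjusted p = 0.000403 against cattle and 0.000164 against yak).

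Both hybrid comparisons share the cattle-yak libraries. Genes called the same way against both parents numbered 10938, with 7140 higher and 3798 lower, and 136 were called opposite ways. Independent lists of these sizes would share 4242 higher and 1296 lower genes. In 20 simulations that gave all groups the same means, shared calls numbered 0. Almost no gene is called where no group differs. The 0 is therefore no chance value for an unchanged hybrid between parents that differ. The fold changes of the 2 comparisons correlated at 0.946 across genes (0.498 in the simulations) with a covariance of 2.61 (0.0166 in the simulations). The simulated comparisons share the cattle-yak libraries too, so their values show what sharing alone gives at the simulated spread. Any departure of the cattle-yak libraries, whatever its cause, enters both comparisons. With median-ratio scaling 4912 genes were higher and 5209 lower against both parents, so 48.5% rather than 65.3% were higher. The contrast with the mean of both parents asks whether the hybrid lies off the mid-parent level on the log scale. There limma called 12392 genes, with 7943 higher and 4449 lower, and 5851 and 5997 after median-ratio scaling (49.4% rather than 64.1% higher).

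**Figure D3:**
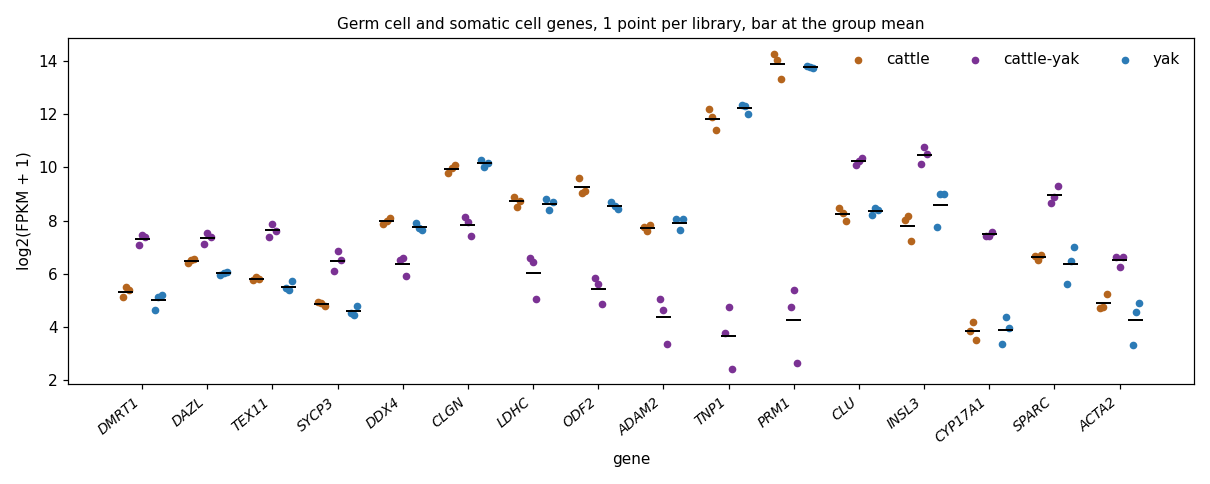
Log2(FPKM + 1) of 16 germ cell and somatic genes in the 9 libraries, with 1 point per library, 3 libraries per group and a bar at each group mean. TNP1 and PRM1 lie lower in every cattle-yak library than in any parent library, and DMRT1, TEX11, CLU, INSL3 and CYP17A1 lie higher.

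Some genes were called against cattle and not against yak. Among genes called higher in this way, IMPA1, an inositol monophosphatase, was at 21.8 ± 0.65 FPKM in cattle, 62.2 ± 9.04 in cattle-yak and 55.6 ± 6.35 in yak, and VGLL3, a transcription cofactor, at 1.5 ± 0.55, 6.73 ± 1.96 and 4.41 ± 0.43. DEFB122A, a beta-defensin of a multigene family whose reads may be shared among copies, was at 317 ± 155, 810 ± 122 and 438 ± 261 FPKM, and median-ratio scaling ended its call (limma, adjusted p = 0.0714). DERA, a deoxyribose-phosphate aldolase, was called at 2.73 ± 0.49 FPKM in cattle and 9.74 ± 1.36 in cattle-yak, but not after median-ratio scaling (adjusted p = 0.0946) nor without cattle replicate 1 or 3 or cattle-yak replicate 3 (limma, adjusted p = 0.0599, 0.0513 and 0.0511). The named genes that were lower were all encoded by the mitochondrial genome. MT-ND3, MT-ND4L and MT-ND6, subunits of complex I, MT-CYB, of complex III, and MT-ATP8, of the ATP synthase, were at 402 ± 159, 108 ± 41.3, 31.6 ± 3.01, 93.1 ± 33.5 and 375 ± 128 FPKM in cattle and at 0.32 ± 0.04, 0.34 ± 0.10, 0.01 ± 0.02, 0.03 ± 0.02 and 0.29 ± 0.11 in cattle-yak.

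Other genes were called against yak and not against cattle. IFI6, an interferon-induced gene, was at 4.33 ± 3.22 FPKM in yak, 39 ± 14.5 in cattle-yak and 17.6 ± 8.56 in cattle (limma, adjusted p = 0.000169 against yak and 0.0529 against cattle). It was called against cattle too without cattle replicate 2 or yak replicate 1 or 3 (limma, adjusted p = 0.0248, 0.0106 and 0.034), and after quantile normalisation or rescaling without the most abundant genes (adjusted p = 0.0465 and 0.0481). The replicate number as a block and a fit of the compared groups alone called it there as well (limma, adjusted p = 0.0115 and 0.0135). OXT, the oxytocin precursor, was at 0.96 ± 0.46 FPKM in yak, 15.6 ± 8.93 in cattle-yak and 15.4 ± 6.65 in cattle, and ALDOC, a glycolytic aldolase, at 3.21 ± 0.78, 19.9 ± 6.66 and 15.45 ± 3.89. C1QA, a complement subunit made by macrophages, was at 6.89 ± 5.04, 45.3 ± 43.9 and 13 ± 2.83 FPKM, and DAPL1 at 2.59 ± 1.78, 15.6 ± 2.65 and 9.99 ± 1.65. Lower in cattle-yak than in yak were GIF, the intrinsic factor that binds vitamin B12, at 44.2 ± 13 FPKM in yak, 4.24 ± 4.54 in cattle-yak and 6.50 ± 0.90 in cattle, and XCL1, KLRG1, VWA5B2 and CES1, which are given with the parent comparison. A call in 1 comparison and not in the other was not tested as a difference between them, although the yak and cattle groups themselves differed in IMPA1, OXT, ALDOC and GIF (limma, adjusted p = 8.43e-05, 0.00117, 0.000786 and 0.00406).

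The parent species were compared with each other to set the scale for the hybrid. Mitochondrially encoded genes led the falls in yak. MT-ATP8 (ENSBTAG00000043564) was at 375 ± 128 FPKM in cattle and 0.16 ± 0.15 in yak, a log2 change of −8.28 ± 0.24 (SE) (limma, adjusted p = 2.14e-08), and MT-ND3 at 402 ± 159 and 0.40 ± 0.29. MT-CO2, a cytochrome c oxidase subunit, was at 1544 ± 378 FPKM in cattle, 8.80 ± 1.47 in yak and 29.8 ± 4.97 in cattle-yak, and ND1 at 420 ± 93.3, 1.95 ± 0.65 and 7.28 ± 1.05. MT-ND4L, MT-CYB and MT-ND6 fell by 6.48, 6.39 and 5.01 on the log2 scale. The genome build named in the submitters' processing notes, UMD3.1, is a cattle build. MC1R (ENSBTAG00000023731), the melanocortin receptor of pigment cells, was at 58.7 ± 11.7 FPKM in cattle, 0.38 ± 0.09 in yak and 4.27 ± 2.31 in cattle-yak. KCNAB1, a potassium channel subunit, was at 42.5 ± 2.30 FPKM in cattle, 0.52 ± 0.09 in yak and 2.42 ± 1.06 in cattle-yak, and EBD, a beta-defensin of the same multigene family, at 30.1 ± 11.3, 0.06 ± 0.10 and 0.91 ± 1.57. Whether yak reads of MC1R, KCNAB1 and EBD map less well to the cattle build was not tested. MT-ATP8 overlaps MT-ATP6 on the mitochondrial genome, so reads of the pair may have been divided and both values are uncertain.

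Among genes higher in yak than in cattle, PREP (ENSBTAG00000016281), a prolyl endopeptidase, was at 54.0 ± 8.95 FPKM in yak, 5.55 ± 1.55 in cattle and 15.9 ± 1.88 in cattle-yak, a log2 change of 3.08 ± 0.18 (SE) between the parents (limma, adjusted p = 3.94e-06). NT5C, a cytosolic nucleotidase, was at 46.5 ± 3.31 FPKM in yak, 4.66 ± 0.40 in cattle and 17.8 ± 2.91 in cattle-yak, and KYAT1, a kynurenine aminotransferase, at 67.0 ± 24.5, 7.83 ± 4.35 and 9.79 ± 3.35. XCL1, a chemokine of activated lymphocytes, was at 10.7 ± 2.15 FPKM in yak against 0.25 ± 0.24 in cattle and 0.24 ± 0.41 in cattle-yak, and KLRG1, a receptor of natural killer and T cells, at 7.05 ± 2.83 against 0.25 ± 0.15 and 0.09 ± 0.10. CES1, a carboxylesterase, VWA5B2, GPR137B, a lysosomal membrane protein, BCAS1, and CADPS, a regulator of vesicle release, rose by between 2.58 and 2.72 on the log2 scale.

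Few germ cell genes were called between the parents. Of the spermatid, acrosome, flagellum, late spermatocyte, piRNA, meiotic and spermatogonial genes, 1, 0, 3, 1, 1, 1 and 0 were higher in yak and 0, 0, 0, 1, 0, 1 and 2 lower, and none of these lists passed camera (adjusted p between 0.502 and 0.756). Extracellular matrix genes were lower in yak as a list, with a median of −0.60 and 4 members, all chosen after their values were seen, lower and 0 higher, a direction kept under the 3 other scalings (camera, adjusted p = 0.0249, and adjusted p = 0.927 with an estimated correlation). These were DCN, LAMB1, COL4A2 and COL1A1, a proteoglycan, a laminin and collagens. In the same order of higher and lower, the counts were 0 and 1 for Sertoli, 0 and 1 for Leydig, 1 and 1 for smooth muscle, 3 and 0 for endothelium, 0 and 3 for macrophages, 1 and 2 for lymphocytes, 1 and 0 for blood, and 0 and 1 for epididymis genes. They were 0 and 1 for apoptosis, 0 and 2 for heat shock, 0 and 0 for immediate early, 1 and 1 for interferon, 0 and 3 for hypoxia and 2 and 2 for housekeeping genes, and the adjusted p of camera for these lists lay between 0.502 and 0.846. Adjusted over the list alone the counts differed for flagellum (1 and 0), piRNA (0 and 0), Sertoli (0 and 0), matrix (0 and 5), lymphocyte (1 and 8) and housekeeping genes (2 and 3). Medians, means and camera differed in sign for meiotic (−0.01, −0.02 and upward), flagellum (−0.03, 0.02 and upward), endothelium (−0.09, 0.13 and upward), blood (−0.19, 0.43 and upward) and epididymis genes (0.05, −0.06 and upward).

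Between yak and cattle limma called 2692 genes, with 1178 higher and 1514 lower in yak, and 1760 without cattle replicate 2. The 2 groups' libraries did not overlap for 5622 genes (39.9%), where chance gives 10%, and the median log2 change of all genes was −0.0562. Of the 2692 genes, the hybrid was called above both parents for 876 and below both for 728. It lay between the parents and was called against both for 136, was called against yak only for 517 and against cattle only for 407, and was called against neither for 28.

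**Figure D4:**
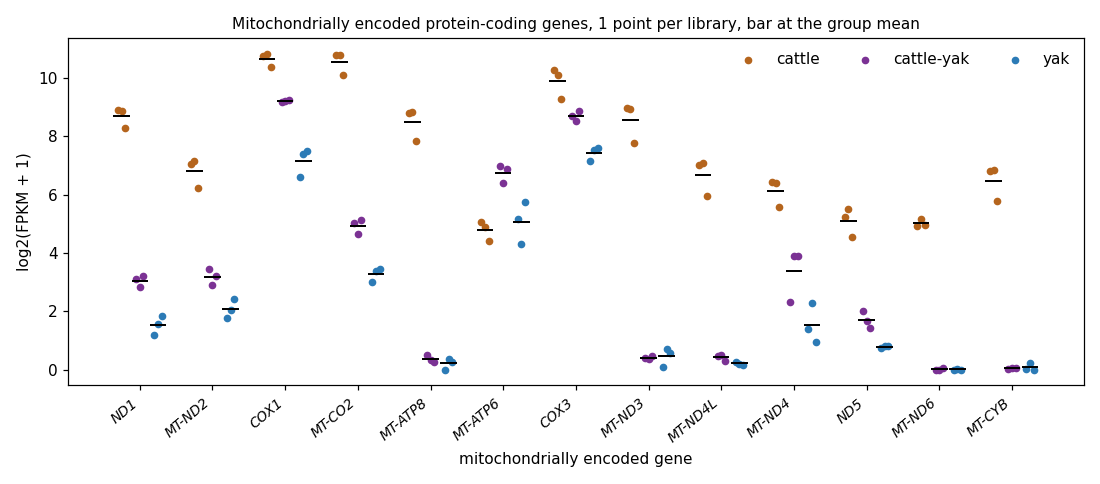
Log2(FPKM + 1) of the 13 mitochondrially encoded protein genes in the 9 libraries, with 1 point per library, 3 libraries per group and a bar at each group mean. In yak 12 of the 13 genes lie below cattle, by up to 8.28 at MT-ATP8, and MT-ATP6, at 35.5 ± 17.1 FPKM against 27.2 ± 6.12, does not.

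For circRNAs the same comparisons were made on read counts. Some circRNAs had reads in every cattle-yak library and none in the parents. The circRNA novel_circ_0022263 had 46, 47 and 83 reads in the cattle-yak libraries and 0 in all 6 parent libraries (edgeR, adjusted p = 0.00014 against cattle and 0.000189 against yak). Likewise novel_circ_0016639 had 20 ± 3 reads and novel_circ_0012105 16 ± 7 reads, with 0 in the parents, and novel_circ_0031019 had 37.7 ± 10.7 reads in cattle-yak, 0 in cattle and 2.67 ± 0.58 in yak. In the opposite direction, novel_circ_0023505 had 70.7 ± 24.3 reads in cattle, 29.7 ± 10.1 in yak and 0 in cattle-yak (edgeR, adjusted p = 4.79e-05 and 0.000153). The table lists circRNAs by such names alone, without a host gene or a position, so what gene each comes from is not given here.

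Other circRNAs followed these patterns. Reads were 0 in all cattle-yak libraries for novel_circ_0018375, with 57 ± 17.4 in cattle and 25.3 ± 5.86 in yak, for novel_circ_0022312, with 44.7 ± 15.2 and 25.3 ± 6.51, for novel_circ_0007439, with 38.7 ± 20.8 and 28 ± 7, and for novel_circ_0020712, with 25.3 ± 16.4 and 30 ± 12.2. The named rise with the highest adjusted p was that of novel_circ_0001739, with 12 ± 4.58 reads in cattle-yak and 0.67 ± 1.15 in each parent (edgeR, adjusted p = 0.0208 against cattle and 0.0242 against yak). It was lost against cattle without cattle replicate 1 or 3 or cattle-yak replicate 2 or 3 (adjusted p = 0.0581, 0.0576, 0.0871 and 0.0535), and against yak without cattle-yak replicate 2 or 3 or yak replicate 1 or 2 (edgeR, adjusted p = 0.0985, 0.0599, 0.0792 and 0.0642). It was also lost with limma on the deposited TPM (adjusted p = 0.0561 against cattle and 0.0565 against yak) and with the replicate number as a block (edgeR, adjusted p = 0.0586 and 0.0721).

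Against cattle, edgeR called 1060 of 3730 circRNAs, with 360 higher and 700 lower in cattle-yak, and against yak 1033, with 386 higher and 647 lower. Of the 700 and 647 lower circRNAs, 283 and 240 had 0 reads in all 3 cattle-yak libraries, and of the 360 and 386 higher, 102 and 149 had 0 reads in all libraries of the parent. Called the same way against both parents were 564, with 121 higher and 443 lower, and 14 were called opposite ways. Of the 121 higher, 13 had 0 reads in both parents, and of the 443 lower, 197 had 0 reads in cattle-yak. Independent lists would share 37 and 121, and the simulations, in which no group differed, shared 0. The correlation of fold changes was 0.65 (0.463 in the simulations) with a covariance of 4.17 (0.25 in the simulations). The simulated comparisons share the cattle-yak libraries too. The groups' reads did not overlap for 1730 circRNAs (46.4%) against cattle and 1752 (47%) against yak. Chance gives 10% for circRNAs kept without regard to group. This table had been filtered on the groups, so its chance value is not known. Against the mean of both parents edgeR called 1229, with 534 higher and 695 lower, and 745 without cattle-yak replicate 3. Library totals without TMM scaling gave 682 higher and 647 lower there, with the median of all circRNAs at 0.29 rather than 0.15 on the log2 scale, so which direction is larger depends on the scaling. They gave 457 higher and 644 lower against cattle, 452 and 600 against yak, and 170 and 406 against both parents. The mean of both parents is taken on the log scale, so a parent at 0 reads lowers it. Thus novel_circ_0021725, with 0 reads in cattle, 19 ± 12.8 in cattle-yak and 32 ± 9.17 in yak, was called higher than this mean. Its log2 change was 2.93 (edgeR, adjusted p = 0.0112). On log counts, the first principal component held 41.5% of the variance and set the cattle-yak libraries apart, and correlations across circRNAs were 0.689 to 0.836 within groups, 0.434 to 0.493 between the parents and 0.258 to 0.422 between cattle-yak and a parent.

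Between the parents, novel_circ_0013863 had 214 ± 19 reads in cattle, 4.67 ± 2.89 in cattle-yak and 0 in yak (edgeR, adjusted p = 2.57e-05). Likewise novel_circ_0015887 had 61.7 ± 2.52 reads in cattle, 3 ± 1 in cattle-yak and 0 in yak, and novel_circ_0007013 and novel_circ_0029365 had 81 ± 38.2 and 75 ± 24.6 reads in cattle and 0 in the other libraries. The reads of novel_circ_0000846 were 94, 115 and 128 in cattle, 336, 284 and 0 in cattle-yak and 0 in yak (edgeR, adjusted p = 0.017), a call lost without yak replicate 1, 2 or 3 (adjusted p = 0.0546, 0.0517 and 0.0535) or with limma on the deposited TPM (adjusted p = 0.0554). In yak and not in cattle, novel_circ_0017989 had 49.3 ± 16.3 reads with 0 in cattle-yak, and novel_circ_0021725 had 32 ± 9.17 with 19 ± 12.8 in cattle-yak. Yak libraries also held 31.7 ± 9.87, 26.3 ± 5.13 and 25.3 ± 3.22 reads of novel_circ_0011052, novel_circ_0003106 and novel_circ_0021745, with 1.33 ± 2.31, 3 ± 2.65 and 1.33 ± 2.31 in cattle-yak and 0 in cattle.

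Between yak and cattle edgeR called 442 circRNAs, with 184 higher and 258 lower in yak. Of the 184 higher, 75 had 0 reads in cattle, and of the 258 lower, 143 had 0 reads in yak. The build named in the processing notes is a cattle build, and whether yak circRNA reads were lost on it was not tested. The count was 293 without cattle replicate 3 and 234, 232 and 233 without yak replicate 1, 2 and 3. The reads did not overlap for 1081 circRNAs (29%). The 10% that chance gives for circRNAs kept without regard to group does not hold here, since the table had been filtered on the groups. Of the 442, the hybrid was above both parents for 8, below both for 22, and between them and called against both for 14. It was called against cattle only for 185, against yak only for 153 and against neither for 60.

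**Figure D5:**
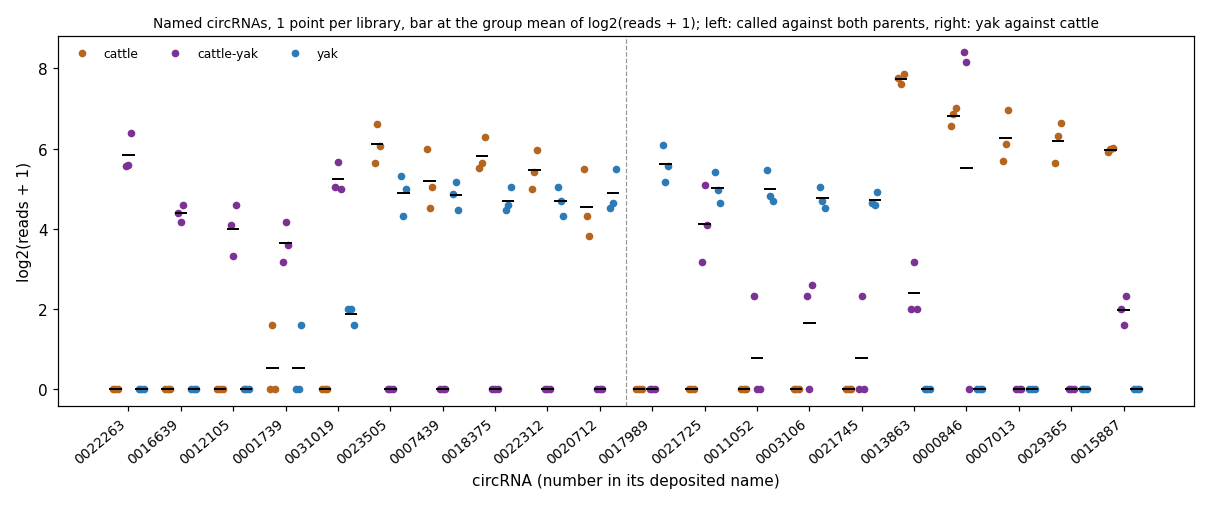
Log2(reads + 1) of the 20 named circRNAs in the 9 libraries, with 1 point per library, 3 libraries per group and a bar at the group mean, to the left those called against both parents and to the right those called between yak and cattle. The 5 circRNAs that were lower in cattle-yak than in both parents have 0 reads in all 3 cattle-yak libraries.

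The number of circRNAs detected was compared per library. Cattle-yak libraries held 4379 ± 43.7 circRNAs with at least 2 reads, cattle libraries 4311 ± 65.9 and yak libraries 4091 ± 48.6 (n = 3 each). The differences were 68 against cattle (exact two-sided permutation p = 0.2), 288 between cattle-yak and yak (exact p = 0.1) and −220 between yak and cattle (exact p = 0.1), where 0.1 is the smallest p that 3 against 3 libraries can give. The 68 fell to 30.3 without cattle replicate 2 and to 43.2 without cattle-yak replicate 2. With at least 5 reads the differences were 236 against cattle and 454 against yak (exact p = 0.3 and 0.1). After thinning each library to 44469 reads, the 3 differences with at least 2 reads were −13.3, 81.3 and −94.7 (exact p = 1, 0.4 and 0.1). Total reads were 58833 ± 7510 in cattle-yak, 52986 ± 2120 in cattle and 48409 ± 4000 in yak libraries (exact p = 0.4 against cattle and 0.2 against yak, and 0.2 between the parents). A loss of yak reads on the cattle build could lower detection in yak and was not tested. Each circRNA in the table had at least 2 reads in all 3 libraries of at least 1 group. Of the 5730, 1497 were present in all libraries of all 3 groups, 1225 in those of cattle-yak only, 804 of cattle only and 618 of yak only, while 554 were shared by cattle-yak and yak, 532 by cattle and yak, and 500 by cattle and cattle-yak. Present means at least 2 reads in all 3 libraries of a group. A circRNA counted for 1 group only may therefore have reads in some libraries of the others. These counts were not adjusted for total reads, whose mean was highest in cattle-yak.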

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

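Each alternative given here was fixed before the data were examined. A minimum absolute log2 fold change of 1 lowered the mRNA counts by its own construction to 7309 genes against cattle, 7895 against yak, 707 between yak and cattle, 7561 against the mean of both parents and 6513 the same way against both parents. Without a filter the circRNA counts were 1743, 1676, 807 and 1909 in the same order of the 4 contrasts, with more circRNAs tested. All other alternatives except the block and the left-out libraries kept the counts within 1.5 times. With the replicate number as a block the mRNA counts were 11805, 12054, 2432, 12291 and 10871 and the circRNA counts 739, 756, 239, 858 and 415. The labels describe the replicates as separate animals. Correlations of same-numbered libraries of 2 groups lay between −0.172 and 0.226 for mRNA and −0.0339 and 0.0438 for circRNAs. For other pairs they lay between −0.352 and 0.23 and between −0.0766 and 0.0582. Of 9 libraries, 2 for mRNA and 4 for circRNAs correlated best with their own number. These values show no clear pairing by number. Leaving out 1 library in turn gave 11565 to 11927, 11801 to 12131, 1760 to 2892, 11989 to 12308 and 10610 to 10808 genes, and 754 to 1029, 703 to 1076, 232 to 415, 745 to 1223 and 377 to 525 circRNAs. The lowest parent counts were 1760 without cattle replicate 2 for mRNA and 293, 234, 232 and 233 without cattle replicate 3 and yak replicates 1, 2 and 3 for circRNAs, and 745 was without cattle-yak replicate 3. Set tests past the threshold numbered 25 of 66, and 0 with an estimated correlation, 23 after quantile normalisation and 25 with a pseudocount of 0.1. Median-ratio scaling turned the log2 change of EPCAM against cattle to −0.44, of DUSP1 to −0.49 against cattle and −0.23 against yak, and of HSP90AA1 and HSPA5 against yak to −0.24 and −0.62, since it lowers all hybrid changes by about the median of all genes. Of the other values of named genes under an alternative, 3576 kept their side of the threshold and direction, 43 lost the call and 21 gained it, and for named circRNAs 490 kept it and 16 lost it. For circRNA detection, at least 5 reads gave differences of 236 and 454 against cattle and yak. With at least 2 reads, thinning gave −13.3, 81.3 and −94.7, and without 1 library the differences were 30.3 to 91.3, 263 to 312 and −258 to −195. The cause of the other changes was not tested. The 3 alternatives for the host gene comparison, a mean of at least 20 reads, 1 circRNA per host gene and a pseudocount of 0.1, were not run. Where a left-out library leaves 2 in a group, the spread is pooled over groups. At the depth and spread of these libraries the circRNA tests called 3% of simulated changes of 1 and 45% of 2 on the log2 scale against cattle. Only 100 circRNAs were changed by each size there, while 28.4% were called in the real data. The adjustment is stricter where few change, so these shares do not give the recovery in the real data.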

Other observations

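The gene groups of the first paragraphs and the tests of the 3 patterns were chosen only after the results were seen, and the splits of the libraries were planned before. Of 77 ribosomal protein genes 53 were called higher and 3 lower in cattle-yak than in cattle, and 55 and 3 against yak, with medians of 0.60 and 0.69 (camera, adjusted p = 0.0133 and 0.0418, and adjusted p = 0.877 and 0.749 with an estimated correlation), but after median-ratio scaling 22 were higher and 19 lower against cattle and 28 and 20 against yak. Of 19 sterol synthesis genes 13 were higher and 4 lower against cattle and 13 and 6 against yak, and the set test was not passed (camera, adjusted p = 0.452 and 0.441). CYP51A1, a sterol demethylase, fell from 77.2 ± 13.5 FPKM in cattle and 108.5 ± 15.9 in yak to 19.4 ± 0.81 in cattle-yak, while MSMO1, a methylsterol oxidase, rose from 27.2 ± 2.09 and 27.3 ± 4.83 to 114 ± 13 and DHCR7, of the last step to cholesterol, from 0.92 ± 0.10 and 1.40 ± 0.26 to 8.21 ± 1.17 (n = 3 each). Of 13 cathepsins 9 were higher and 2 lower against each parent (camera, adjusted p = 0.452 and 0.441). CTSD, a lysosomal protease, rose from 52.4 ± 8.50 and 34 ± 10.4 to 207 ± 23.5 FPKM, and CTSF, another cathepsin, fell from 199.7 ± 22.8 and 193.7 ± 7.28 to 56.8 ± 12.1. Of 4 beta-defensins 3 were higher against cattle and 2 against yak, and of 40 proteasome genes 25 were higher and 10 lower against cattle and 24 and 9 against yak, with 12 and 17 and 9 and 17 after median-ratio scaling.

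Between the parents, 14 of 46 nuclear-encoded complex I genes were higher in yak and 3 lower, with a median of 0.25 (camera, adjusted p = 7.39e-05, and adjusted p = 0.477 with an estimated correlation), and of 37 other nuclear-encoded respiratory chain genes 6 were higher and 0 lower (camera, adjusted p = 0.000951, and adjusted p = 0.626 with an estimated correlation). Some genes that act in pigment cells were also measured. TYR, the enzyme of the first step of melanin synthesis, was at 18.8 ± 2.07 FPKM in cattle, 17.6 ± 1.91 in yak and 1.17 ± 0.53 in cattle-yak. MLANA, a melanosome protein, was at 6.97 ± 2.28, 0.44 ± 0.27 and 0.04 ± 0.06, and ASIP, an antagonist of the melanocortin receptor, at 6.64 ± 3.65, 0.23 ± 0.23 and 32.8 ± 11.3 FPKM in the same order.

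Whether other splits of the libraries give as many calls was counted. For each pairwise comparison 1 of the 10 splits of its 6 libraries, the real one, gave as many, which is too few splits for a share under 0.05. The real counts were 11894, 12116 and 2692 genes with a highest other count of 0, 0 and 1, and 1060, 1033 and 442 circRNAs with a highest other count of 1, 0 and 1. Against the mean of both parents 1 of 100 drawn partitions of the 9 libraries, the real one, gave as many as 12392 genes, and the highest other count was 11655, and for 1229 circRNAs 1 of 100 and 725. For calls the same way against both parents 1 of 100 gave as many as 10938 genes, with 10736 as the highest other, and for 564 circRNAs 1 of 100 and 328. A share of 1 in 100 makes a random partition of the libraries an unlikely source of the mRNA counts. The circRNA table had been filtered on the real groups, which favours the real partition, so the circRNA shares cannot decide this. Neither share bears on differences between the groups other than hybrid status. The high other counts come from a structure of the samples: 5 other drawn partitions kept the 3 cattle-yak libraries together, and the highest counts of partitions that parted them were 258 and 77 genes and 103 and 17 circRNAs.

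Spermatid, acrosome and flagellum genes were lower in the cattle-yak libraries, with 86 of 87 members called lower against both parents. The scaling of the libraries is argued against, since 86 was the lowest number under 3 other scalings. Yak alleles that map less well to a cattle genome are argued against as well, since the members' median between yak and cattle was 0.0357 (quartiles −0.116 to 0.239) while it was −4.14 between cattle-yak and cattle. A candidate explanation that stays open is that late germ cells were fewer in the hybrid testes, and lower expression within such cells is as open, since whole tissue was measured. A difference between the groups other than hybrid status, such as season or handling, was not tested.

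In 7 somatic marker lists 87 of 106 members were called higher in the cattle-yak libraries than in both parents, though the endothelium, macrophage and lymphocyte lists did not pass camera against either parent. Scaling alone is argued against as the whole cause, since the lowest number under 3 other scalings was 69, with median-ratio scaling. The lists differed from each other by more than members moved between lists at random (100000 permutations, permutation p = 0.00328, and 0.00022 on ranks, which was added after the first p was seen). The permutation treats genes as independent, while the estimated correlation within these lists lay between 0.35 for endothelium and 0.636 for matrix. Some members, such as AIF1, also fell. The test therefore cannot decide whether a lower share of germ cells raised every somatic type alike. With a pseudocount of 0.1 the list medians against the mean of both parents were 2.28 for Leydig, 2.09 for matrix, 1.94 for Sertoli, 1.75 for smooth muscle, 1.63 for macrophage, 1.55 for endothelium and 1.22 for lymphocyte genes. A lower germ cell share, alone or together with a change within some somatic types, may account for the higher somatic markers and stays open.

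Mitochondrially encoded genes were lower in the yak and cattle-yak libraries, in each for 12 of 13 genes, and MT-ATP6 was called higher in cattle-yak than in cattle, at 108 ± 21.6 and 27.2 ± 6.12 FPKM. Mitochondrial transcripts that differ from the cattle reference are a candidate explanation: across the 13 genes the mean levels of cattle-yak and yak, given those of cattle, had a partial Spearman rho of 0.98 (permutation p = 1e-05, the smallest the permutations can give), a test chosen after the values were seen, and a lower level of yak mitochondrial transcripts would give the same. Fewer mitochondria or less mitochondrial RNA per cell is argued against as the whole cause, since the changes between yak and cattle spanned 8.55 on the log2 scale, from 0.28 to −8.28, and 5.64 without the overlapping MT-ATP6 and MT-ATP8, with a largest SE of 0.46. Against yak 8 of the 13 genes were called higher in cattle-yak and 0 lower, such as COX1 at 593 ± 15.1 and 146 ± 44.7 FPKM. Of all genes tested 7794 of 14091 were called higher there. The set test was not passed (camera, adjusted p = 0.441, and adjusted p = 0.749 with an estimated correlation). These calls therefore cannot decide whether differences from the reference shared by both groups are the whole cause. How the reads were assigned to mitochondrial genes stays open. Cattle mitochondria in the hybrids would give reads that map as those of the cattle libraries do, and the values argue against that. Across the 13 genes the mean levels of cattle-yak had a Spearman rho of 0.973 with yak and 0.423 with cattle. MT-CO2 was at 29.8 ± 4.97 FPKM in cattle-yak, 8.80 ± 1.47 in yak and 1544 ± 378 in cattle, while MT-ATP6 was higher in cattle-yak than in cattle.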
